A study of Mus musculus with 12 samples.

How the data were processed

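Gene expression was measured on 12 Affymetrix mouse arrays, 1 per sample, in cultured endothelial cells from newborn wild-type mice. Per the labels, 4 samples were mock-transfected controls, 4 carried a stably transfected, non-cleavable transmembrane form of murine tumour necrosis factor (tmTNF, chronic exposure), and 4 were treated with soluble TNF at 20 ng/ml for 4 h (acute exposure). About 5 micrograms of total RNA went onto each array, per the labels. The labels do not state whether the replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Replicate numbers were given in accession order and pair no samples.

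The deposited values are background-corrected signal intensities on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes. No MAS5 version or setting is given in the sources used here. The deposited values ran from 0.1 to 95672, and every array had a 2% trimmed mean of 1000, so each array had been scaled as a whole. Scanner files and detection calls were not used here. The 4 arrays in each group are the depth behind each comparison.

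Each array was rescaled to a 2% trimmed mean of 500 without the 64 control probe sets, and log2(signal + 16) was taken. Of 45101 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none in the platform annotation. Gene identifiers were matched to the RefSeq gene table of assembly GRCm38.p6, which was used for names only. It held 34754 of the identifiers, and 0 symbols changed. No coordinates are given, because the array values name no genome build. Probe sets were kept where at least 4 arrays reached a signal of 100 (19591 probe sets), and each gene was represented by the probe set with the highest mean, which left 10269 genes. Among the 125 genes called between tmTNF and soluble TNF, 2 had another probe set of the opposite sign, and 0 had one past the threshold.

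The 3 groups were fitted in one model with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the 10269 genes and a threshold of 0.05. All fold changes are on the log2(signal + 16) scale, which understates changes of dim genes. Adjusted p-values in the text are from this limma fit, and the values after ± are standard errors (SE) of log2 fold changes or standard deviations (SD) of signals, as stated. Where all 4 arrays of the dimmer group lay under 100, the difference is given as "at least N-fold", the brighter group's mean log2 value against that of a signal of 100. Detection flags were not used, so 100 stands in for the background limit. Gene lists were compared with all other genes by limma's camera with a preset correlation of 0.01 and with an estimated correlation, and tested on their own by fry, with adjustment over the 29 lists that had at least 5 measured members. Camera with the preset correlation passed 9 lists for tmTNF minus control. It passed 7 for soluble TNF minus control and 7 for tmTNF minus soluble TNF. Fry passed 3 in each comparison. The model was tested on simulated data with 200 changed genes. For tmTNF minus control it recovered 30, 62, 90 and 96 percent of genes changed by a log2 value of 1, 2, 3 and 4, with 10 false calls among 149. For soluble TNF minus control the shares were 28, 76, 88 and 92 percent with 3 false calls among 145, and for tmTNF minus soluble TNF 26, 68, 88 and 92 percent with 7 among 144. The simulated genes were drawn independently, without the structure that real arrays share, so these shares of false calls may not hold for the real data.

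Groups, tests, 33 gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, up to 10 genes per direction called in both exposures, up to 4 called members of each list, the brightest member of a list with none, and always Tnf, Tnfrsf1a, Tnfrsf1b, Sele, Vcam1, Icam1, Ccl2 and Nos3. Predicted genes without an approved symbol were passed over. Not every gene named by the rule is given in the text for every comparison. There were 3 departures in the choice of genes, all made after values had been seen. List members past the threshold only when adjusted over the list alone were added. Genes with an unadjusted p under 0.05 in both exposures were added, 5 per direction. The brightest members of lists without a call were left out of the results tracked across the alternatives. They were also left out of the text, apart from genes named there for another reason. They made 81 pairs of gene and comparison, of which 0 passed the threshold, and 128 of their 2187 values under the alternatives changed sign.

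Alternatives were other scalings (quantile, same median, none), pseudocounts of 1 and 64, no filter and a filter at 250, other ways of merging probe sets, a fit on only the 2 groups compared, eBayes without a trend, array weights, leaving out each array, an adjusted p of 0.01, a minimum of 2-fold, and controls split between comparisons. An endothelial identity score as a covariate, and the omission of 3 arrays with low scores, were added after seeing the data. Comparisons against the same controls were set beside 100 simulations of unchanged groups. The closing section gives the effect of each alternative.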

Results

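Endothelial cells from newborn mice were profiled in 3 groups of 4 arrays: mock-transfected controls, cells that stably carried a non-cleavable transmembrane TNF (tmTNF), and cells given soluble TNF at 20 ng/ml for 4 h. TNF is an inflammatory cytokine that acts on endothelium through the receptors Tnfrsf1a and Tnfrsf1b. The design asks what long and short exposure have in common and where they part. Between 17652 and 19174 probe sets per array reached a signal of 100. The Actb 3' to 5' signal ratio was 1.185 to 1.291 on control arrays, 1.119 to 1.29 on tmTNF arrays and 1.101 to 1.156 on soluble TNF arrays, which all lay below the controls. The 18S ribosomal RNA control probe set differed by group, with means of 131 ± 10.7 in controls, 311.3 ± 143 in tmTNF cells and 387.9 ± 90 in soluble TNF cells (signal, SD, n = 4 each). Correlations between arrays, across genes that are not independent replicates, were 0.744 to 0.881 within controls, 0.796 to 0.939 within tmTNF and 0.877 to 0.983 within soluble TNF.

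Tnf, the transfected gene, had 1 probe set, which stayed under the signal of 100 on all 12 arrays. The Tnf signals were 7.3 to 25.7 in controls, 6.2 to 14.3 in soluble TNF cells, and 13.8, 10.0, 77.2 and 62.1 in tmTNF replicates 1 to 4. The sources used here do not say whether the transfected construct includes the part this probe set covers, so the Tnf signal checks neither the transfection nor the labels. Tnfrsf1a and Tnfrsf1b did not pass the threshold in any comparison. The log2 fold change of Tnfrsf1a was -0.20 ± 0.31 (SE) in tmTNF and -1.12 ± 0.31 in soluble TNF, each against control, and that of Tnfrsf1b was 0.83 ± 0.48 and -0.65 ± 0.48.

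Cells with tmTNF had higher levels of interferon-induced genes than control cells. Zbp1, a cytosolic nucleic acid sensor, rose by a log2 fold change of 5.62 ± 0.83 (SE, n = 4 per group, adjusted p = 0.0134). Its control signals were 19, 7.8, 178.7 and 18.7, mostly under 100, so the size of that rise is uncertain. Oas2, an antiviral oligoadenylate synthetase, rose 9.2-fold (log2 3.20 ± 0.43, adjusted p = 0.0063), Ddx60, an antiviral helicase, 9.96-fold (adjusted p = 0.00461) and Ifit3, an interferon-induced antiviral protein, 8.63-fold (adjusted p = 0.0183). Icam1, the leukocyte adhesion receptor, was at least 7.14-fold higher, with a mean signal of 1121 ± 1036 (SD) against 13.6 ± 10.0 in controls (adjusted p = 0.00492). Il13ra1, a subunit of the interleukin 13 receptor, was the 1 gene that fell, and was at least 7.9-fold lower (signal 31.3 ± 33.0 against 1007 ± 543, adjusted p = 0.00461).

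In total 20 genes passed the threshold between tmTNF and control, 19 higher and 1 lower. The called genes also included Ifi44l, an interferon-induced gene (at least 4.45-fold higher), C1ra, a protease of the classical complement pathway (at least 5.2-fold), Klhl4 (at least 6.14-fold), and Stat2, a transcription factor of interferon signalling (log2 1.75 ± 0.26, adjusted p = 0.0134). The Y-linked genes Eif2s3y (at least 7.36-fold), Kdm5d (at least 3.46-fold) and Uty (at least 2.49-fold) were higher too. These 3 genes gave signals of 218.8 or more on every tmTNF array and 39.5 or less on the 8 other arrays, so every difference of tmTNF from another group ran alongside this difference in Y-linked signal. At an unadjusted p under 0.05 there were 776 genes, with 513 expected by chance. The 4 arrays of one group lay wholly above or below the other in 3.17% of all genes, and chance gives 2.86%.

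Interferon-stimulated genes rose as a group in tmTNF cells. Over all genes tested 5 of the 47 measured members rose, and 41 rose when adjusted over the list alone, with all 47 higher than in control. The list had a median log2 fold change of 2.00 (1.95 with its 1 dim gene at its bound) and passed camera (adjusted p = 4.69e-49; adjusted p = 0.0382 with an estimated correlation) and fry (adjusted p = 0.00421). Iigp1 and Gbp2, interferon-inducible GTPases, had values of 3.42 ± 0.61 and 3.40 ± 0.70, and both rose when adjusted over the list alone. Genes of MHC class I presentation, which load peptides for T cells, gave 0 of 18 over all genes and 10 of 18 adjusted over the list alone. These included Nlrc5, the transactivator of MHC class I genes (2.19 ± 0.51), and the immunoproteasome subunits Psmb9 (2.17 ± 0.58) and Psmb10 (2.12 ± 0.43), and the list passed camera (adjusted p = 7.26e-13; adjusted p = 0.112 with an estimated correlation) and fry (adjusted p = 0.0289). Beside these gene groups, 0 of 5 measured leukocyte markers passed over all genes or adjusted over the list alone, with a median of 1.74 and a mean of 1.10 (camera adjusted p = 0.19).

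Chemokines, which recruit leukocytes, gave 0 of 15 over all genes and 7 of 15 adjusted over the list alone in tmTNF cells. These included Ccl5 (4.40 ± 0.95), Cxcl10 (4.30 ± 0.94), Cxcl11 (at least 6.61-fold) and Ccl7 (4.16 ± 1.27), and the median of the list was 1.36 (0.94 with 3 dim genes at their bounds; 1.078 without tmTNF replicate 4 and 2.165 without tmTNF replicate 1). The chemokine list passed camera (adjusted p = 4.8e-07; adjusted p = 0.112 with an estimated correlation). Ccl2 had a value of 2.87 and did not pass over all genes. Genes of the NF-kB pathway, the transcription factor system that TNF receptors activate, gave 0 of 21 over all genes and 4 of 21 adjusted over the list alone. These were Nfkbie (3.03 ± 0.84), Birc3 (1.96 ± 0.45), Tnip1 (1.52 ± 0.29) and Nfkb2 (0.87 ± 0.26). The NF-kB list passed camera (adjusted p = 0.000367, and adjusted p = 0.259 with an estimated correlation) but not fry (adjusted p = 0.108). Its median was 0.19, and 0.59 without tmTNF replicate 1, whose NF-kB score of -0.401 lay within the control range (-0.831 to -0.374), while the other tmTNF arrays scored 0.122 to 0.571. Vcam1, another leukocyte adhesion molecule, had a value of 3.75 ± 1.17 and did not pass (adjusted p = 0.366), and neither did Sele, the endothelial selectin (1.07 ± 0.86, adjusted p = 0.881; 0.3975 without control replicate 2 and 1.5588 without control replicate 4), nor Nos3, the endothelial nitric oxide synthase (-0.48 ± 0.78, adjusted p = 0.946).

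Smaller shifts of lists were also found in tmTNF cells by camera, each lost with an estimated correlation. Cholesterol and fatty acid synthesis genes were shifted upward (median 0.39, adjusted p = 0.00187; adjusted p = 0.21 with an estimated correlation). Of its 27 measured members 0 passed over all genes and 1, Lss, which makes lanosterol, rose adjusted over the list alone. TGF-beta and BMP signalling genes were shifted upward (median 0.39, adjusted p = 0.0434; adjusted p = 0.332 with an estimated correlation), with 0 of 33 called either way. The lists shifted downward were cell cycle (0 of 60 called, median -0.23, adjusted p = 0.00187; adjusted p = 0.788 with an estimated correlation), oxidative phosphorylation (0 of 49, median -0.07, adjusted p = 0.00187; adjusted p = 0.417 with an estimated correlation) and coagulation (0 of 17, median -0.54, adjusted p = 0.0494; adjusted p = 0.21 with an estimated correlation). Without control replicate 4 the cell cycle list turned direction, with a median of 0.09. Leaving out 1 array, the coagulation median ran from -0.602 to -0.228 (camera passed in 6 of 12 fits), TGF-beta and BMP from 0.212 to 0.59 (9 of 12), oxidative phosphorylation from -0.163 to -0.048 (11 of 12) and cholesterol and fatty acid synthesis from 0.25 to 0.572 (12 of 12).

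The number of genes called between tmTNF and control depended on single arrays. It was 66 without tmTNF replicate 1, and 4 without control replicate 3 and tmTNF replicates 2 and 4, which had the lowest endothelial identity scores (an omission chosen after seeing the data). Without these 3 arrays, adjusted over the list alone, the 7 chemokines became 0 and the 10 MHC class I genes became 0, while 36 of the 47 interferon-stimulated genes passed. Leaving out 1 array at a time, Zbp1 and Stat2 kept their call in 10 of the 12 fits and Ifit3 in 8.

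**Figure D1:**
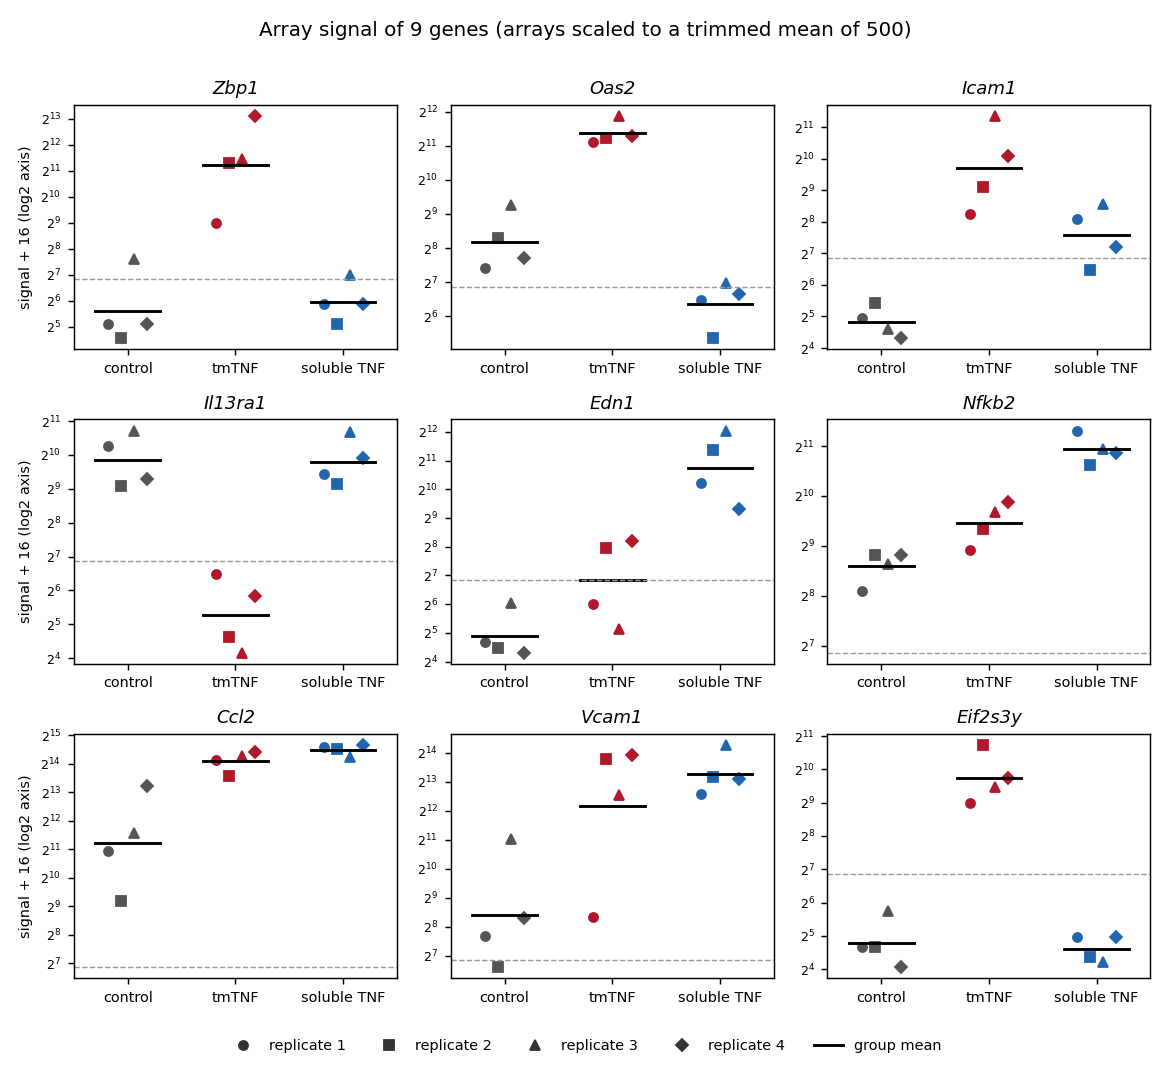
Signal of 9 genes on each of the 12 arrays, on a log2 axis of signal + 16, by group (control, tmTNF, soluble TNF), with the bar at the geometric mean of each group and the dashed line at a signal of 100. Eif2s3y lies above the line on the 4 tmTNF arrays only, and Edn1 has its highest group mean with soluble TNF (signal 2153).

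Cells treated with soluble TNF for 4 h had higher levels of 4 genes than control cells. Edn1, which encodes the vasoconstrictor endothelin 1, was at least 14.7-fold higher (signal 2153 ± 1607 against 17.3 ± 21.4, SD, n = 4 per group, adjusted p = 0.0202). Rgs16, a brake on G protein signalling, rose 20.8-fold (log2 4.38 ± 0.57 SE, adjusted p = 0.0202). Nfkb2, the p100 subunit of NF-kB, rose 5.11-fold (log2 2.35 ± 0.26, adjusted p = 0.0103). Slc12a2, a sodium, potassium and chloride cotransporter, rose 3.76-fold (log2 1.91 ± 0.27, adjusted p = 0.0359).

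These 4 genes were all that passed the threshold between soluble TNF and control. At an unadjusted p under 0.05 there were 1303 genes, 555 higher and 748 lower, with 513 expected by chance. Groups did not overlap in 8.11% of genes, and chance gives 2.86%. The NF-kB list gave 1 of 21 over all genes and 10 of 21 adjusted over the list alone. These included inhibitors that feed back on the pathway, Nfkbie (3.71 ± 0.84) and Tnfaip3 (2.97 ± 0.52), and the subunit Relb (1.98 ± 0.46). The median was 0.69, and the list passed camera (adjusted p = 1.41e-07; adjusted p = 0.122 with an estimated correlation) and fry (adjusted p = 0.0319). Chemokines gave 0 of 15 over all genes and 5 of 15 adjusted over the list alone, among them Ccl2, which attracts monocytes (3.27 ± 0.61), Cxcl12 (3.12 ± 0.67) and Cx3cl1 (2.86 ± 0.86). Their median was 1.59, with camera adjusted p = 4.79e-07 (adjusted p = 0.122 with an estimated correlation) and fry adjusted p = 0.034. Leukocyte adhesion molecules gave 0 of 18 over all genes and 2 of 18 adjusted over the list alone, Vcam1 (4.87 ± 1.17) and Icam1 (at least 1.66-fold). That list did not pass camera (adjusted p = 0.164). Sele and Nos3 did not pass over all genes. The mean log2 value of Sele was 11.584 ± 1.265 (SD) against 9.033 ± 1.639 in controls. For Nos3 it was 12.97 ± 0.174 against 13.035 ± 1.407.

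In the angiogenesis list after soluble TNF, 1 of 38 rose over all genes (Edn1) and 4 of 38 adjusted over the list alone, with Thbs1, an inhibitor of vessel growth (4.51 ± 0.98), and the matricellular proteins Ccn1 (3.09 ± 0.73) and Ccn2 (2.44 ± 0.49). Its median was -0.04 and its mean 0.29, opposite in sign, and camera did not pass (adjusted p = 0.365). The TGF-beta and BMP list gave 0 of 33 over all genes and 3 of 33 adjusted over the list alone, Tgfb2, Smad6 (1.79 ± 0.40) and Smurf2 (1.11 ± 0.29). It was shifted upward by camera (adjusted p = 0.00373, and adjusted p = 0.302 with an estimated correlation) but did not pass fry (adjusted p = 0.193). Survival genes gave 0 of 18 over all genes and 2 of 18 adjusted over the list alone, Tnfaip3 and Birc3 (camera adjusted p = 0.00515; adjusted p = 0.122 with an estimated correlation). Cell cycle genes were shifted upward by camera (median 0.60, adjusted p = 4.71e-06; adjusted p = 0.675 with an estimated correlation), as were oxidative phosphorylation genes (median 0.13, adjusted p = 0.00279; adjusted p = 0.612 with an estimated correlation) and ribosomal protein genes (median 0.06, adjusted p = 0.0186; adjusted p = 0.675 with an estimated correlation). In each of these last 3 lists 0 members passed over all genes or adjusted over the list alone. Leaving out 1 array, their medians ran from 0.315 to 0.963 for cell cycle (camera passed in 12 of 12 fits), from 0.072 to 0.164 for oxidative phosphorylation (11 of 12) and from 0.029 to 0.113 for ribosomal proteins (9 of 12). Interferon-stimulated genes gave 0 of 47 either way, with a median of -0.09 (camera adjusted p = 0.95).

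The 4 calls with soluble TNF were often lost when a single array was left out. Their number was 1 without control replicate 1, 1 without control replicate 2, 22 without control replicate 4, 0 without soluble TNF replicate 1, 1 without replicate 2, 0 without replicate 3 and 2 without replicate 4. Of the 12 fits leaving out 1 array, Nfkb2 kept its call in 10, Edn1 in 7, Rgs16 in 5 and Slc12a2 in 1. The effect sizes moved little in these fits. The lowest absolute log2 fold change was 2.19 for Nfkb2, 5.42 for Edn1, 4.07 for Rgs16 and 1.74 for Slc12a2. Slc12a2 also lost its call without each of the 4 tmTNF arrays, which enter this comparison only through the shared model. The 5 chemokines became 3 without control replicate 1, 2 without control replicate 2, 3 without soluble TNF replicate 1 and 3 without soluble TNF replicate 4.

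**Figure D2:**
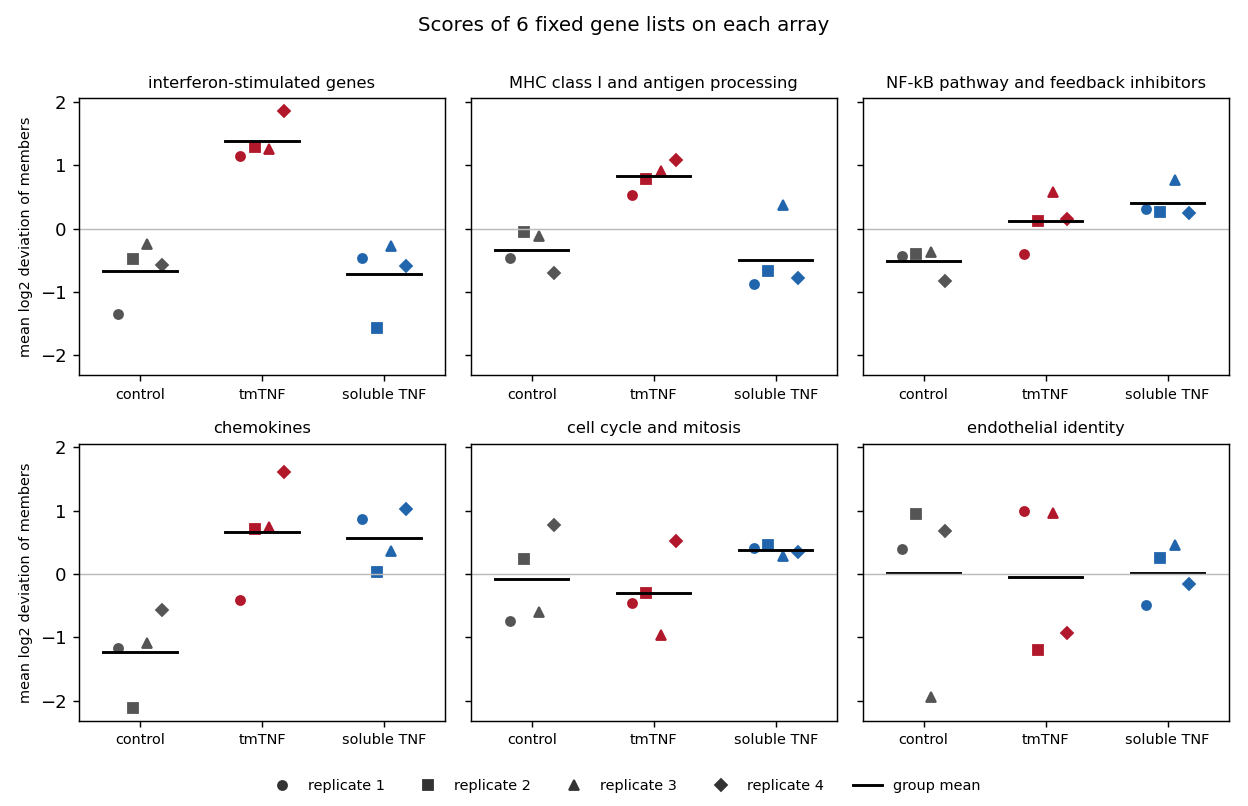
Mean log2 deviation of 6 gene lists on each of the 12 arrays, by group, with the bar at the group mean. Interferon-stimulated genes lie higher on the tmTNF arrays, and endothelial identity is low on control replicate 3 (-1.946), tmTNF replicate 2 (-1.201) and tmTNF replicate 4 (-0.929).

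Set directly against each other, tmTNF cells had 18 of 47 interferon-stimulated genes and 3 of 18 MHC class I genes called higher over all genes. Both lists passed camera, but not with an estimated correlation. Soluble TNF cells had higher Edn1 and Ccn2. Oas2 was 32.2-fold higher with tmTNF (log2 5.01 ± 0.43 SE, n = 4 per group, adjusted p = 0.000631). Irf7, a transcription factor that amplifies interferon responses, was 17.8-fold higher (log2 4.15 ± 0.57, adjusted p = 0.00488). Lower with tmTNF were Edn1 (log2 -3.90 ± 0.76, adjusted p = 0.0349), Ccn2 (-3.15 ± 0.49, adjusted p = 0.0127) and Fbln2, a matrix glycoprotein (-3.64 ± 0.65, adjusted p = 0.0232). Il13ra1 was at least 7.6-fold lower with tmTNF (adjusted p = 0.00208).

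In this comparison 125 genes passed, 98 higher and 27 lower with tmTNF. With arrays scaled to the same median the split was 67 higher and 173 lower of 240, since that scaling moved the median of all genes from 0.08 to -0.15 (and from 0.03 to -0.12 for tmTNF minus control). At an unadjusted p under 0.05 there were 2041 genes, with 513 expected by chance, and groups did not overlap in 16.1% of genes, where chance gives 2.86%. Further genes higher with tmTNF were Zbp1 (5.26 ± 0.83), Oas3 (4.52 ± 0.96), Isg20, an exonuclease (3.85 ± 0.77), Usp18, which removes the ubiquitin-like protein Isg15 (3.54 ± 0.69), and Trim14 (at least 3.3-fold). The Y-linked genes Eif2s3y and Kdm5d were at least 7.36-fold and 3.46-fold higher with tmTNF. Genes lower with tmTNF were Rgs16 (-3.41 ± 0.57), Tslp, an alarmin cytokine (-2.43 ± 0.50), Smurf2, a ubiquitin ligase of TGF-beta signalling (-1.52 ± 0.29), Ehd1 (-1.49 ± 0.25), Nfkb2 (-1.49 ± 0.26), Prps2 (-1.46 ± 0.26) and Arsj, a sulfatase (at least 4.3-fold lower).

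Interferon-stimulated genes were higher with tmTNF in 18 of 47 members over all genes and 37 of 47 adjusted over the list alone. The median was 1.95 (1.85 with 2 dim genes at their bounds), with camera adjusted p = 6.45e-25 (adjusted p = 0.289 with an estimated correlation) and fry adjusted p = 0.00334. MHC class I genes gave 3 of 18 over all genes, Nlrc5 (3.38 ± 0.52), H2-T24 (3.30 ± 0.49) and the peptide transporter Tap1 (1.87 ± 0.41), and 12 of 18 adjusted over the list alone. That list had camera adjusted p = 2.01e-07 (adjusted p = 0.446 with an estimated correlation) and fry adjusted p = 0.0181. Complement and acute phase genes gave 1 of 10 over all genes, C1ra, and 3 of 10 adjusted over the list alone with Cfb and Saa3 (camera adjusted p = 0.0188; adjusted p = 0.446 with an estimated correlation; fry adjusted p = 0.0344). NF-kB genes were shifted downward in tmTNF against soluble TNF, with 1 of 21 lower over all genes (Nfkb2) and 4 of 21 adjusted over the list alone. The NF-kB list had camera adjusted p = 0.0242 (adjusted p = 0.583 with an estimated correlation) and did not pass fry (adjusted p = 0.276). Leaving out 1 array, it passed camera in 10 of 12 fits, and Nfkb2 kept its call in 7. Leukocyte markers gave 0 of 5 either way, with a median of 1.89 (camera adjusted p = 0.26).

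Lists of proliferation and energy genes were shifted downward by camera, relative to other genes, in tmTNF against soluble TNF, each lost with an estimated correlation. Cell cycle genes had a median of -0.90 with 0 of 60 called either way (adjusted p = 2.41e-10; adjusted p = 0.583 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.23 (adjusted p = 3.13e-07; adjusted p = 0.446 with an estimated correlation), with 1 of 49 lower over all genes, the complex I subunit Ndufb8 (-1.01 ± 0.18), and 2 of 49 adjusted over the list alone. Ribosomal protein genes had a median of -0.11 with 0 of 31 called (adjusted p = 0.000942; adjusted p = 0.592 with an estimated correlation). That median ran from -0.183 to -0.062 leaving out 1 array, and was -0.017 without the 3 arrays with the lowest endothelial scores. Klf9, a transcription factor, was the 1 of 34 early-response genes called over all genes and adjusted over the list alone, higher with tmTNF (2.34 ± 0.47), and that list did not pass camera (adjusted p = 0.146). Angiogenesis genes gave 2 of 38 lower over all genes, Edn1 and Ccn2, and 4 of 38 adjusted over the list alone, and their median of 0.14 had the opposite sign to their mean of -0.22 (camera adjusted p = 0.434). Matrix proteases gave 0 of 23 over all genes, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0728).

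The count of 125 moved with single arrays. It was 233 without control replicate 1, 198, 31, 49 and 70 without tmTNF replicates 1, 2, 3 and 4, and 42, 28, 55 and 57 without soluble TNF replicates 1, 2, 3 and 4. Without control replicate 3 and tmTNF replicates 2 and 4 together it was 154, with 48 of the 125 kept. Leaving out 1 array at a time, Tslp and Oas3 kept their call in 3 of the 12 fits, Tap1 in 4, Smurf2 and Usp18 in 5, and Edn1, Fbln2, Isg20, Klf9, Prps2 and Arsj in 6.

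No gene passed the limma threshold in both exposures against control (0 genes). At an unadjusted p under 0.05 in both, 81 genes were higher in both, 33 were lower in both and 29 went opposite ways. Among the genes higher in both were Acod1, an itaconate-producing enzyme (at least 4.2-fold in tmTNF and at least 3.84-fold in soluble TNF), Vcam1, Cxcl10 (4.30 and 3.15), Nfkbie and Traf1, an adaptor of TNF receptor signalling (at least 1.82-fold and at least 1.94-fold). These are group means. On tmTNF replicate 1 the signals of Acod1 (17.8), Vcam1 (311), Nfkbie (752.7) and Traf1 (7) lay within the control range, and that of Cxcl10 (773) above it. Traf1 was also under 100 on tmTNF replicate 3 (88.7). Among genes lower in both were Klk8, a serine protease (-3.37 ± 0.60 and -2.68 ± 0.60), and Lrg1 (-2.43 ± 0.99 and -3.47 ± 0.99). Among the opposite ones were Oas2 (3.20 and -1.81 ± 0.43), H2-T24 (1.36 ± 0.49 and -1.94 ± 0.49) and Trim30d (1.51 and -1.56).

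Unchanged groups simulated against the same controls gave 38.8 genes higher in both on average (57 at most), 31.8 lower in both (49 at most) and 0.52 opposite (3 at most). The simulated arrays drew each gene independently, so the highest values may understate the spread in real data. Independent lists would give 26.7, 20.5 and 51.2. With the controls split between the comparisons the counts were 30 to 37 higher in both, 8 to 12 lower in both and 37 to 527 opposite over 6 splits. Across genes, which are not independent replicates, the log2 fold changes of the exposures correlated with r = 0.209, against 0.502 in simulation (0.545 at most) and -0.374 to -0.005 with split controls. Their covariance was 0.0727 against a simulated 0.128, an excess of -0.0549. The number of genes called in both was 2 without control replicate 4, and the 81 became 130 without control replicate 3 and 46 without tmTNF replicate 4. The r of 0.209 became 0.377 without control replicate 3 and 0.07 without tmTNF replicate 4.

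**Figure D3:**
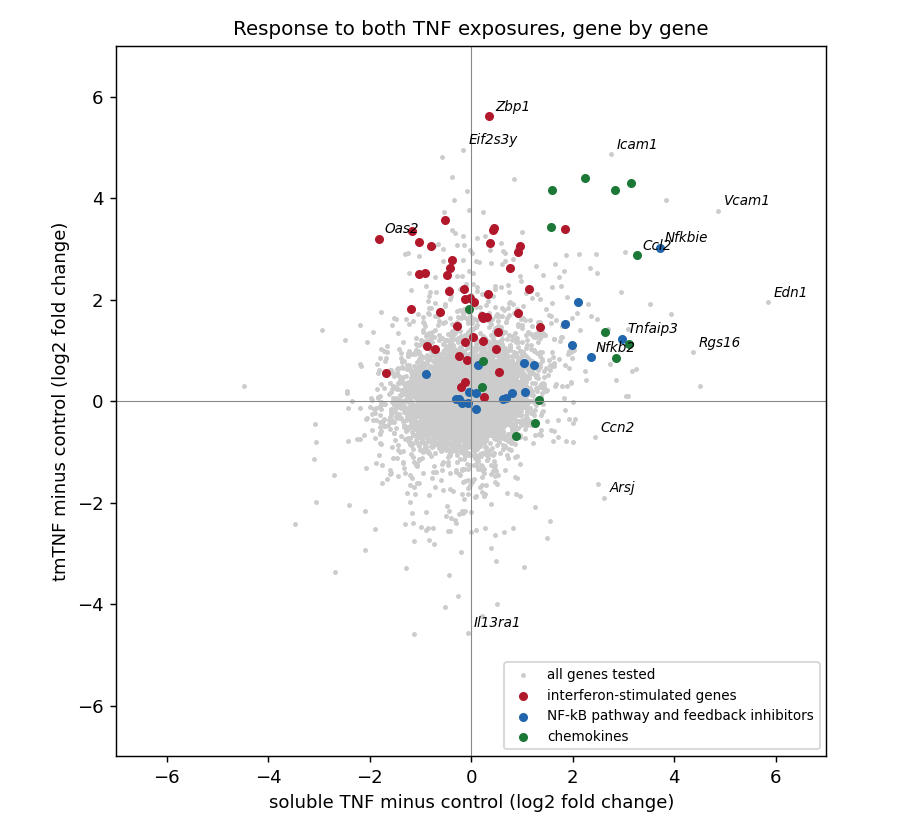
Log2 fold change of each of the 10269 genes with soluble TNF (horizontal axis) against that with tmTNF (vertical axis), each against control, with members of 3 lists coloured. Interferon-stimulated genes lie high on the vertical axis only (medians 2.00 and -0.09), and r over all genes is 0.209.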

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

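The tests of other splits, scaling, leukocyte RNA, the endothelial score, TNF exposure, degraded RNA and keratins were chosen after the result was seen, while those of X-linked escape genes and the mesothelial score were written before theirs.

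Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, gave signals of 218.8 or more on the 4 tmTNF arrays and of 39.5 or less on the 8 others. A swap of labels was not tested, as the pattern was itself defined by the labels. A candidate explanation is that the tmTNF cells descend from male cells and the others from cells without an expressed Y chromosome. Female cells in the other groups, with both copies of escape genes expressed, cannot be told apart from other origins: the median log2 fold change of Kdm6a, Kdm5c, Ddx3x and Pbdc1 was -0.132 against control and -0.141 against soluble TNF, between the bounds set beforehand. Eif2s3x was left out of that set because it had been seen before. Its values of -0.364 ± 0.154 (SE) against control (adjusted p = 0.623) and -0.715 ± 0.154 against soluble TNF (adjusted p = 0.0479) go with female cells in the other groups. That call was kept in 2 of 12 fits leaving out 1 array (adjusted p up to 0.151). Xist, a gene of X inactivation, stayed under 100 on all 12 arrays (16.8 to 62.5), so it gave no sign of female cells in any group. Its 1 probe set used, near background, cannot settle this. The Y-linked signal coincided with the tmTNF group, so a part of cell origin in the other tmTNF differences, if origin differed, stays open.

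Interferon-stimulated genes were higher with tmTNF than in either other group, though against soluble TNF the list did not pass camera with an estimated correlation (adjusted p = 0.289). Scaling is argued against as the whole cause by a median log2 fold change of at least 1.721 under each scaling in both comparisons. With the endothelial identity score as a covariate the median was 1.976 against control, and 43 of 47 members passed adjusted over the list alone. Only 0.112% of the variance of that score lay between groups, so the covariate could hardly move the median. This test therefore cannot decide on the spread in endothelial identity. Leukocyte RNA is argued against by 0 of 6 abundant leukocyte genes (Ptprc, Laptm5, Coro1a, Tyrobp, Fcer1g, Cd52) at 100 on more than 1 tmTNF array, their highest signal there being 84.9. By contrast, the 5 measured leukocyte markers had a median of 1.74 in tmTNF minus control, with 3 higher, 2 lower and 0 past the threshold. Cd68, a leukocyte gene outside those 6, had high signals on some arrays of both groups. They were 6727.6, 722.9, 4295.2 and 63.3 on tmTNF replicates 1 to 4, and 18210, 520.1, 2284.9 and 255.2 on control replicates 1 to 4. Some leukocyte RNA is therefore not excluded. A response to chronic TNF may account for the pattern, as may an origin of the tmTNF cells other than that of the controls, if there was one. The controls were mock-transfected, which argues against the transfection procedure alone, but the labels do not say whether they carried a construct without TNF. None of these was tested.

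Endothelial identity genes, 40 measured, were low on control replicate 3 (score -1.946), tmTNF replicate 2 (-1.201) and tmTNF replicate 4 (-0.929), while the 9 other arrays lay between -0.482 and 0.996. TNF exposure is argued against by the 0.112% of the variance of the score that lay between groups (18.2% by chance), and degraded RNA by 0 of the 3 arrays with an Actb or Gapdh 3' to 5' ratio above all 9 others. The margin was narrow. Actb ratios were 1.283 on control replicate 3 and 1.29 on tmTNF replicate 2, against 1.291 on control replicate 2, whose endothelial score was 0.955. On tmTNF replicate 4 the Actb ratio was 1.119. Mesothelial cells, as a share or in place of most endothelial cells, cannot be told apart from other causes, since the values go both ways. Msln, Krt19 and Aldh1a1, which led to this idea and were left out of its marker list, were high on the 3 arrays (1288.5 or more, 5563.7 or more and 3839.5 or more), against at most 1578.1, 3244 and 132.3 on the 9 others. Efemp1 (108.2 or more against at most 31.5) and, on both tmTNF arrays, Slpi (1125 and 4849.7) go the same way. Other keratins do not: with Krt19 counted, 1 of 4 reached 100 on any of the 3 arrays, and Krt7, Krt8 and Krt18 stayed at 64.8 or less. Of the marker list, Wt1, Upk3b, Upk1b, Lrrn4, Muc16, Nkain4, Bnc1, Gpm6a and Rspo1 also stayed under 100 on the 3 arrays (Wt1 at most 45.7). The mesothelial score was above the rest of its group on 1 of the 3 arrays, which met the bound written beforehand, but that bound was a poor one: the score rests on 3 of 16 listed genes, and Cldn15 among them followed the endothelial score (r = 0.94 over the 12 arrays), a reason found after the value was seen. A difference between cell preparations may be the cause and stays open, and it was not tested.

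Other splits of the 8 arrays bear on whether chance can be excluded. For tmTNF against control, 4 of 35 splits gave as many as the real 20 genes, so chance was not excluded, and the highest other gave 381 (control replicates 1 and 3 with tmTNF replicates 2 and 4 on one side). That count, far above the real one, points to a structure of the samples that the groups do not explain. The arrays on that side had the 4 lowest endothelial identity scores of the 8. These were -1.946, -1.201, -0.929 and, on control replicate 1, 0.399, against 0.687 to 0.996 on the other side. For soluble TNF against control, 3 of 35 splits gave as many as the real 4 genes, so chance was not excluded. The highest other gave 249 (control replicates 1 and 2 with soluble TNF replicates 2 and 3), again a structure of the samples. The fibroblast marker score divided these 8 arrays in the same way, across both groups. It was low on control replicates 1 and 2 (-1.429 and -0.766) and soluble TNF replicates 2 and 3 (-0.932 and -1.311). On control replicates 3 and 4 (1.551 and 1.171) and soluble TNF replicates 1 and 4 (1.776 and 1.836) it was high. Whether a share of fibroblasts lay behind this split was not tested. The labels do not say whether arrays on one side, such as soluble TNF replicates 1 and 4, share a culture. For tmTNF against soluble TNF, 1 of 35 splits, the real one with 125 genes, reached that number, and the highest other gave 0. With 35 splits this is the smallest share the test can give, and the test was chosen after the result was seen. It argues against chance there but does not exclude it.

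Single arrays far from the other 3 of their group were found 24 times in 408 groups tested, where chance gives about 1 in 20, or 20. Soluble TNF replicate 3 was the array with the most, 6: Tnip1 (signal 8576, others 3673 to 4209), Psmb8 (4936), Gbp6 (1350), Lrg1 (178) and the scores of the NF-kB (0.77) and MHC class I (0.375) lists. Control replicate 4 was low in the NF-kB (-0.831) and ribosomal protein (-0.056) scores and high in Vcl (6905). Control replicate 2 was low in the leukocyte marker score (-1.42) and Oasl1 (138.8, others 864.9 to 1048) and high in Tnip1 (1719). Control replicate 3 was high in Csf1 (4222) and low in H2-T24 (160.7), and control replicate 1 was high in Klk8 (2171). Soluble TNF replicate 2 was low in Tnfrsf1b (107), Igtp (299.8) and Trim30d (120.5), soluble TNF replicate 1 in Tgfbr1 (414.4), and soluble TNF replicate 4 was high in Kdm5d (18.5, under the signal of 100). Among tmTNF arrays, replicate 1 was low in the complement score (-0.647), replicate 3 high in the erythroid and platelet score (0.653) and in Arsj (23.1, under 100), and replicate 4 high in Iigp1 (9090).

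Outside the genes compared, the 18S ribosomal RNA control probe set averaged 311.3 on tmTNF and 387.9 on soluble TNF arrays, with every array of both groups above the controls (121.3 to 146.3). Among probe sets without a single gene, 5 were higher with tmTNF than in control, 0 differed between soluble TNF and control, and 36 were higher and 7 lower with tmTNF than with soluble TNF.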

How the results depend on the processing

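The endothelial score as a covariate and the omission of control replicate 3 and tmTNF replicates 2 and 4 together were tests chosen after the result was seen, and the rest were planned. No paired analysis was possible because the labels give no replicate numbers. Counts were pooled over genes called in each comparison, genes called in both exposures, and list members that passed adjusted over the list alone. The pooled counts stayed within 1.5 times the main value in 262 alternatives and moved further in 44. The counts of genes called in each comparison, given below, moved further in a larger share of their alternatives than the pooled counts did. Values of single genes kept direction and side of the threshold in 3882 alternatives, lost the call in 237, gained one in 143 and reversed in 11, and lists tested by camera kept it in 573, lost it in 47 and reversed in 1. The cause was not tested except where named.

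For tmTNF against control (20 genes) the count was 45 with every probe set on its own (more features tested), 13 at an adjusted p of 0.01, 51 with the endothelial covariate (all 20 genes kept), 4 without the 3 arrays (3 of the 20 kept), and 16 to 66 leaving out 1 array, highest without tmTNF replicate 1. Of the 20 genes, 14 passed in all 12 such fits. Zbp1 lost its call without control replicate 4 or tmTNF replicate 2, and Stat2 without control replicate 4 or tmTNF replicate 4 (adjusted p up to 0.0619 for both). Ifit3 lost it without control replicates 1 or 4 or tmTNF replicates 2 or 4 (up to 0.0805). For soluble TNF against control (4 genes) it was 2 with only those 2 groups fitted, 0 at 0.01, 12 with the covariate, 17 without the 3 arrays and 0 to 22 leaving out 1: 1 without control replicate 1, 1 without control replicate 2, 22 without control replicate 4, and 0, 1, 0 and 2 without soluble TNF replicates 1 to 4. In these 12 fits Nfkb2 passed in 10 (adjusted p up to 0.0682), Edn1 in 7 and Rgs16 in 5 (up to 0.125 for both) and Slc12a2 in 1 (up to 0.174). For tmTNF against soluble TNF (125 genes) it was 240 with arrays scaled to the same median, 259 with every probe set, 439 with only those 2 groups, 1176 with array weights, 20 at 0.01, 381 with the covariate, 154 without the 3 arrays (48 of the 125 kept) and 28 to 233 leaving out 1: 233 without control replicate 1, 198, 31, 49 and 70 without tmTNF replicates 1 to 4, and 42, 28, 55 and 57 without soluble TNF replicates 1 to 4. Of the 125 genes 25 passed in all 12 fits. Tslp and Oas3 passed in 3 (adjusted p up to 0.123 and 0.141) and Tap1 in 4 (up to 0.151). Genes called in both exposures (0) became 1 with the covariate, 5 with control replicates 2 and 4 set against tmTNF and the others against soluble TNF, and 0 to 2 leaving out 1 (2 without control replicate 4).

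Adjusted over the list alone, the 7 chemokines in tmTNF became 4 with the filter at 250 (fewer genes) and 0 without the 3 arrays (list median 1.362 before, 0.957 after, with fewer arrays), and the 10 MHC class I genes became 5 at 0.01 and 0 without the 3 arrays (list median 1.35 before, 1.149 after). The 5 chemokines in soluble TNF became 8 with no filter (more genes), 2 at 0.01 and 2 to 7 leaving out 1 (3, 2, 3 and 3 without control replicates 1 and 2 and soluble TNF replicates 1 and 4). Interferon-stimulated genes stayed at 37 to 42 of 47 in tmTNF against control leaving out 1, and 33 to 40 against soluble TNF, and were 36 and 31 without the 3 arrays. Leaving out 1 array, lists lost camera in tmTNF against control for coagulation (6 of 12 fits passed), TGF-beta and BMP (9), cell cycle (9) and oxidative phosphorylation (11), in soluble TNF against control for ribosomal proteins (9) and oxidative phosphorylation (11), and in tmTNF against soluble TNF for NF-kB (10, median -0.473 to -0.192).

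Reversed values were all of genes that had not passed, except the cell cycle list. In tmTNF minus control, Tnfrsf1a turned to 0.056 without tmTNF replicate 2 (range -0.39 to 0.056) and 0.17 without the 3 arrays, Nos3 to 0.27 without the 3 arrays, and the cell cycle median to 0.091 without control replicate 4 (range -0.55 to 0.091). In soluble TNF minus control, Nos3 turned to 0.022 with arrays scaled to the same median, and to 0.33, 0.02 and 0.12 without control replicates 1, 2 and 4 (range -0.74 to 0.33). In tmTNF minus soluble TNF, Nos3 turned to 0.060 without tmTNF replicate 2, 0.058 without tmTNF replicate 4 (range -0.97 to 0.060) and 1.01 without the 3 arrays, and Vcam1 to 0.15 without tmTNF replicate 1 (range -1.71 to 0.15). Brightest members of lists with no called gene were not tracked here, a choice made after 128 of their 2187 values had been seen to change sign. Signal over background limits the dimmest genes: those under 100 in a whole group have only a bound. Some genes with 1 array over 100 in the dimmer group are given without a bound, and their sizes are uncertain too. Examples are Zbp1 in controls (up to 178.7), Lrg1 with soluble TNF (3.1, 4.4, 178 and 4.6) and Cfb in controls (5.9, 4.8, 110.7 and 62.1).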

Other observations

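The genes below were picked by the rule fixed before the values were seen, extended afterwards to members that passed when adjusted over the list alone, and no further test was chosen after the result was seen.

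In the list of extracellular matrix structure 0 of 31 fell over all genes and 2 of 31 fell adjusted over the list alone against control, Fbln2 (-3.15 ± 0.65, SE, n = 4 per group) and Col6a3, a chain of collagen VI (-2.27 ± 0.61). The median of that list was 0.19 and its mean 0.03 while camera pointed down without passing (adjusted p = 0.656). Itga1, the collagen-binding integrin chain, was at least 3.65-fold higher, the 1 of 19 integrins that rose adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.881). Il7, a lymphocyte growth factor, was at least 2.53-fold higher, the 1 of 9 cytokines that rose adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.07). Complement and acute phase genes gave 1 of 10 over all genes, C1ra, and 2 of 10 adjusted over the list alone, with Cfb, complement factor B (4.13 ± 1.19), and did not pass camera (adjusted p = 0.0513).

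Between the exposures, 0 of 23 matrix proteases and inhibitors passed over all genes. Adjusted over the list alone, Mmp3 (3.80 ± 1.29) and Mmp13 (at least 6.35-fold) were higher with tmTNF, while Timp1, their inhibitor, was lower (-1.51 ± 0.44). The highest signals of both lay on tmTNF replicates 2 and 4, the tmTNF arrays with low endothelial scores. On tmTNF replicates 1 to 4 Mmp13 signals were 38.7, 15704.6, 257.4 and 1239.2, against 4.9 to 70.6 with soluble TNF. Those of Mmp3 were 102.8, 5436.3, 424.6 and 12817.1, against 34.3 to 261.6. Replicates 1 and 3 lay within the control range for both genes. Control replicate 3, also low in endothelial score, had 288.2 for Mmp13 and 257.4 for Mmp3. A part of cell composition in this difference was not tested. Leaving out 1 array, the log2 fold change ran from 2.698 to 5.42 for Mmp13 and from 2.73 to 4.98 for Mmp3. The stress response genes Herpud1 (2.83-fold) and Chac1 (5.1-fold) were higher with tmTNF adjusted over the list alone, 2 of 32, with 0 over all genes (camera adjusted p = 0.076). Acta2, smooth muscle actin, was lower with tmTNF than with soluble TNF (-2.81 ± 0.63), the 1 of 4 measured smooth muscle and pericyte markers that passed adjusted over the list alone, with 0 over all genes. Endothelial identity genes gave 0 of 40 over all genes and adjusted over the list alone in each of the 3 comparisons, with medians of -0.05, 0.11 and -0.04 for tmTNF minus control, soluble TNF minus control and tmTNF minus soluble TNF. Fibroblast markers gave 0 of 9 and lymphatic markers 0 of 6 in each comparison, but their scores spread widely within groups. The fibroblast score had an SD of 1.453 in controls and 1.698 with soluble TNF. The lymphatic score ran from -2.101 to 1.851 on tmTNF arrays. Against soluble TNF, 7 of 9 fibroblast markers were lower with tmTNF and 2 higher (median -0.77, camera adjusted p = 0.146). The counts of 0 therefore do not show that the cultures held the same cells.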
